A study of Mus musculus with 18 samples.

How the data were processed

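The values used were the deposited RMA values of 18 Affymetrix mouse arrays, 22690 probe sets on each, of which 64 Affymetrix controls were left out and 22626 tested. Per the submitters' processing notes the authors computed them by RMA in log2, and the range of the deposited values, 2.83 to 14.15, fits that unit. The RMA version and settings are not given in the sources used here. Raw image files were not used here, and no value was normalized again in the results of the report. The groups were taken from the sample titles. For 8 of the 9 INS37217 arrays the source name speaks of saline only. For 1 array, saline 7 d replicate 2, the source name gives 2 h, but it correlated best with INS37217 7 d replicate 2 (0.9945) and saline 7 d replicate 3 (0.9941), against at most 0.979 with any saline 2 h array. It was kept at 7 d.

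Whether replicate numbers pair the arrays across groups was checked on the values. After the mean of each group was removed, the 45 pairs of arrays with the same number correlated at 0.426 to 0.921, the pairs of replicate 1 with 2 or 3 at -0.501 to -0.847, and the pairs of replicate 2 with 3 at 0.363 to 0.725. For 17 of 18 arrays the closest arrays on average were those of the same number. Within a group replicate 1 correlated with the others at 0.9591 to 0.981, and replicates 2 and 3 with each other at 0.9941 to 0.9966. The SD of the log2 values was 1.80 to 1.89 on replicate 1 arrays and 1.91 to 2.00 on the others, and the medians were 6.67 to 6.76. What the numbers stand for, such as a batch or a day, is not given in the sources used here. The test without the block was fixed before the data were examined and kept, and the block value stands beside it.

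Differences were tested with limma 3.58.1 in R 4.3.3: lmFit and eBayes on all 18 arrays with 1 mean for each of 6 groups, contrasts between the means, and p values adjusted by Benjamini and Hochberg over the 22626 probe sets, with adjusted p under 0.05 as the threshold. The residual degrees of freedom were 12 (10 with the block) and the prior ones 3.3 (10.5). Gene lists, 16 of functions and 12 of cell type markers, were tested with limma camera at an inter-gene correlation of 0.01, and again with the correlation estimated, adjusted over 28 lists and 10 contrasts (280 tests). Every p in the text comes from limma or limma camera unless an exact permutation test is named. A list given as passed without a second p also passed with the estimated correlation. The first p printed for a list is that at 0.01, which can be too small where the genes of a list vary together more than that. Its size is therefore not a measure of the strength of a shift. With 3 arrays per group, the number of arrays limits the precision.

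Gene names came from the probe-to-gene table of the array and a RefSeq gene table: 20380 probe sets had 1 gene, 691 several and 1555 none, for 12393 genes. Probe sets with several genes or none were tested but are not named. A gene was represented by the probe set of highest mean over all arrays, while counts of named genes take any of its probe sets. Chosen for naming were, for each contrast, up to 10 genes per direction with the largest change among those that passed with group ranges apart, up to 4 members of largest change per list, and Gfap, Fgf2, Mip, Aqp1, Aqp4, P2ry2, Cryaa and Cryab always. The text gives only some of the genes so chosen. A few further genes that did not pass without the block are given as values beside their list, and they were chosen after the values were seen. Genes in 2 lists were Aqp4, Car14, Car2 and Kcnj10 (Mueller glia and transport), Mip (transport and lens) and Slc16a8 (transport and pigment epithelium).

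The steps were tested on simulated data of 22626 probe sets, with 67, 67 and 66 of them changed by log2 0.5, 1 and 2. For INS37217 against saline at 24 h the test without the block found 11.9% of changes of log2 0.5, 59.7% of 1 and 98.5% of 2, with 0 false among 113 calls, and with the block 61.2%, 100% and 100%, with 12 false among 186. For saline at 24 h against 2 h it found 14.9%, 50.7% and 98.5% without the block, with 0 false among 109 calls, and 53.7%, 98.5% and 100% with it, with 6 false among 174. The simulated arrays carried a replicate effect estimated from the real ones, but added alike in every group and with independent noise. That is the model of the block itself, so the simulation favours the block and does not show its gain on the real arrays.

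The alternatives tried were quantile normalization again, equal array medians, only the probe sets above the median level, eBayes with trend and robust, only the arrays of the groups compared, the block, the mean of the probe sets of a gene, each array left out in turn, and for lists an estimated correlation. Added after the arrays were seen were only replicates 2 and 3, and the block on those arrays for the 2 h comparison. The omission of saline 7 d replicate 2 was already among the single omissions. The share of identical values between 2 arrays of a group was 0.712% to 2.79%.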

Results

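Retinal detachment was produced in Balb/cJ mice by an injection of 1 uL under the retina, either of saline or of saline with 10 uM INS37217. INS37217, also known as denufosol, is an agonist of the P2Y2 nucleotide receptor, which drives fluid out of the subretinal space across the pigment epithelium. Retinas were taken at 2 h, at 24 h, when they had reattached but were still misfolded, and at 7 d, when the folds had gone and function was incomplete. Each array held a pool of more than 5 retinas, 3 arrays per treatment and time, 18 in all, and per the design text the 3 are biological replicates. No untreated retina was analysed here, so every value compares injected retinas with injected retinas. All changes are log2 differences between groups of n = 3 arrays, with the standard error (SE) and the p from limma adjusted over 22626 probe sets.

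Time after injection and replicate number separated the arrays far more than INS37217 did. The first principal component held 49.9% of the variance and mainly set replicate 1 of every group apart from replicates 2 and 3. The next 2 components, 21% and 9.15% of the variance, followed time. Arrays of the same replicate number were alike across groups, so each comparison is also given with the replicate number added to the model, called the block below. With the block more probe sets passed in all 10 comparisons, and every probe set that passed without it passed with it.

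**Figure D1:**
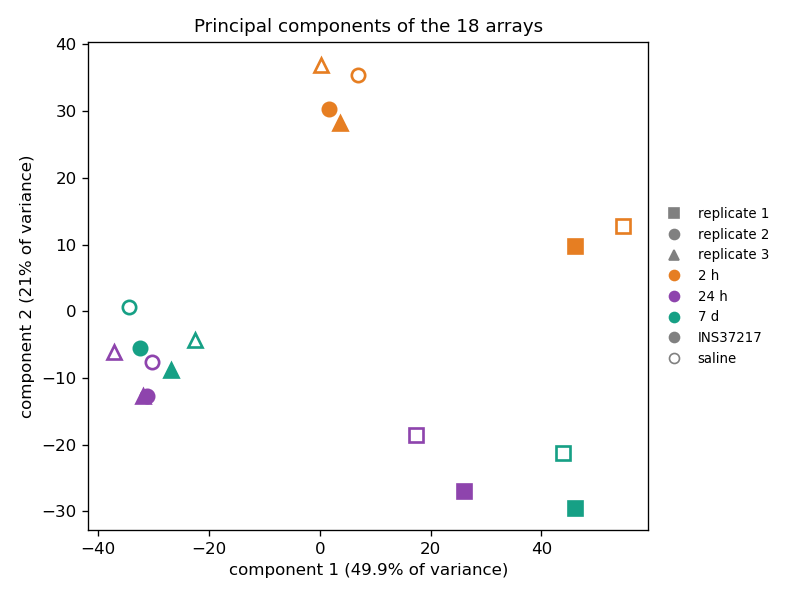
First against second principal component of the 18 arrays (49.9% and 21% of the variance), with the colour for the time, open symbols for saline, filled symbols for INS37217 and squares for replicate 1. The replicate 1 arrays lie at the right, and the times are spread along the second component.

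The first comparison asked which genes differ 2 h after injection when INS37217 is given. Lens genes were higher, immediate early genes were lower, and Alas2 of erythroid cells and Pmel and Tyrp1 of pigment cells fell in the INS37217 retinas. Crygd, which encodes a crystallin of lens fibres, rose by 1.15 (SE 0.14, adjusted p = 0.0039, n = 3). Bfsp1, a filament protein of lens fibres, rose by 0.97 (SE 0.16, adjusted p = 0.024), and Crybb1 by 0.72 (SE 0.11, adjusted p = 0.012). All 19 measured lens genes were higher, with a median of 0.58 (camera adjusted p = 3.3e-61). Of them 7 rose, 16 rose adjusted over the list alone, and 15 rose with the block. Crystallins are close in sequence, so probe sets of 1 member can also bind another. The mean of the list was 9.99 in the saline 2 h group, 10.59 in the INS37217 2 h group and 10.62 to 10.88 in the 4 later groups.

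Pmel and Tyrp1 fell within a pigment epithelium list that did not shift as a whole. Pmel, whose product forms the fibrils of melanosomes, fell by 1.22 (SE 0.13, adjusted p = 0.0015). Tyrp1, an enzyme of melanin synthesis, fell by 1.01 (SE 0.16, adjusted p = 0.015), and Gpnmb, a glycoprotein of melanosomes and macrophages, by 0.58 (SE 0.10, adjusted p = 0.024). Dct, another melanin enzyme, stood at -0.90 (SE 0.22, adjusted p = 0.24, and 8.8e-06 with the block). The list did not pass (camera adjusted p = 0.072). Of its 13 genes 2 fell, and adjusted over the list alone 4 fell and 1 rose. Its median was 0.16, while its mean, -0.19, and the camera direction were lower. Rpe65 and Rgr of this list had higher means with INS37217, 8.29 against 7.97 and 8.41 against 8.01. Of other tissues, Dcn of fibroblasts (6.68 against 7.81) and Acta2 of vessel walls (8.75 against 9.23) had lower means. Their lists moved less, fibroblasts 6.35 against 6.44 and endothelium and pericytes 6.54 against 6.66. Whether the pools held unequal amounts of such tissue was not tested. Alas2, the first enzyme of haem synthesis in erythroid cells, fell by 1.37 (SE 0.18, adjusted p = 0.0049), and it alone of 3 measured erythrocyte genes passed and carried the list (median -0.18, camera adjusted p = 3.2e-05), with Slc4a1 at -0.18 (SE 0.17) and Hba-a1 at -0.08 (SE 0.20).

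Immediate early genes, many of them transcription factors, which are switched on within minutes of injury, were lower together with INS37217 (median -0.27, camera adjusted p = 2.5e-11). With limma 0 of 29 passed over all probe sets and 12 had an unadjusted p under 0.05, while 9 fell and 1 rose adjusted over the list alone, as with the block. Egr2 stood at -1.04 (SE 0.21, adjusted p = 0.074, and 0.00023 with the block). Nr4a1 stood at -1.03 (SE 0.21, adjusted p = 0.089, and 7.9e-06 with the block). Reactive glia genes were higher (median 0.33, camera adjusted p = 2.6e-13). In that list 1 of 18 genes rose, and 4 rose adjusted over the list alone. The riser was Lcn2, an iron-carrier binding protein (0.79, SE 0.11, adjusted p = 0.0084). Gfap of this list did not pass, with means of 7.62 with INS37217 and 7.47 with saline. Cytokine, chemokine and adhesion genes were higher as a list (median 0.22, camera adjusted p = 1.5e-06), with 0 of 24 past limma, 4 at unadjusted p under 0.05 and 1 riser adjusted over the list alone. Icam1, which holds leukocytes on vessel walls, stood at 0.56 (SE 0.11, adjusted p = 0.057, and 0.0018 with the block).

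Genes outside these lists also passed at 2 h. Ch25h, which makes the antiviral oxysterol 25-hydroxycholesterol, rose by 0.72 (SE 0.13, adjusted p = 0.04). Agt, the precursor of angiotensin, rose by 0.69 (SE 0.10, adjusted p = 0.011). Aldh18a1, an enzyme of proline synthesis, fell by 0.60 (SE 0.10, adjusted p = 0.033), with -0.6 to -0.26 over its 5 probe sets, of which 1 passed. Heat shock and oxidative stress genes were higher (median 0.11, camera adjusted p = 2.3e-07, but adjusted p = 0.082 with an estimated correlation), with 6 of 22 risers adjusted over the list alone. Hspa1b, an inducible chaperone, stood at 0.92 (SE 0.18, adjusted p = 0.072, and 0.00094 with the block). Sample quality moved with the groups: the 3' minus 5' signal of beta-actin was 1.04 (SD 0.0929) in the saline 2 h group and 0.747 (SD 0.0416) in the INS37217 2 h group, exact permutation p = 0.1, the smallest 3 against 3 arrays can give. In the other 4 groups it was 0.603 to 0.65.

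In all, 29 probe sets passed at 2 h, 21 higher and 8 lower, for 15 and 7 named genes. With the block 398 passed (312 higher, 86 lower), with only replicates 2 and 3 304, and with only the 6 arrays of the groups compared 0 in limma (812 at unadjusted p under 0.05). The count was 8 to 19 with any 1 of the 6 arrays left out, and of the named genes given here only Crygd, Alas2 and Pmel passed each time.

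The next comparison asked what INS37217 changes at 24 h, when the retina is reattached but folded. Interferon-induced genes, which block viral replication or present antigen, were higher with INS37217, together with genes of complement and reactive glia. Slfn4, an interferon-induced gene of myeloid cells, rose by 2.74 (6.70-fold, SE 0.19, adjusted p = 6.2e-06, n = 3). Its saline 24 h values, 5.03 to 5.11, lay below the mean of the extraocular muscle list there, 5.29, so the fold is approximate. That list is only a rough guide to background, here and below, since its member Pvalb had a mean of 8.02 in that group. The Slfn4 values of the saline 2 h group were lower, 3.96 to 4.11. Oasl2, of the oligoadenylate synthetase family, rose by 1.46 (SE 0.14, adjusted p = 0.00018). Rsad2, an antiviral enzyme, rose by 1.24 (SE 0.15, adjusted p = 0.0015), Ifit1, which binds viral RNA, by 1.19 (SE 0.16, adjusted p = 0.0042), and Ifi44l by 1.28 (SE 0.18, adjusted p = 0.0069), with 0.15 to 1.28 over its probe sets. All 22 measured genes of the interferon and antigen presentation list were higher, with a median of 0.59 (camera adjusted p = 7.8e-46). Of them 5 rose, 17 rose adjusted over the list alone, and 15 rose with the block.

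Single genes of neutrophils, complement, reactive glia and macrophages also rose at 24 h. S100a9, a calcium-binding protein of neutrophils, rose by 1.62 (SE 0.26, adjusted p = 0.024), while its partner S100a8 stood at 1.48 (SE 0.30, adjusted p = 0.095, and 0.00082 with the block). The neutrophil list was higher (median 0.22, camera adjusted p = 9.9e-07, but adjusted p = 0.12 with an estimated correlation), with 1 riser of 12. Cfb, a protease of the alternative complement pathway, rose by 1.33 (SE 0.17, adjusted p = 0.0042), and C1ra by 0.65 (SE 0.12, adjusted p = 0.043). They were the 2 risers of 11 complement genes (median 0.17, camera adjusted p = 7.8e-06), a list that stood at -0.11 with only probe sets above the median level (adjusted p = 1). Lcn2 rose by 1.30 (SE 0.11, adjusted p = 7.3e-05), the 1 riser of 18 reactive glia genes, where 4 rose adjusted over the list alone (median 0.27, camera adjusted p = 1.5e-10). Gfap of that list did not pass, with means of 8.61 with INS37217 and 8.64 with saline. Chil1, a chitinase-like protein of inflamed tissue, rose by 1.17 (SE 0.19, adjusted p = 0.024), and Mmp3, a matrix protease, by 1.27 (SE 0.21, adjusted p = 0.026). Fcer1g, the signalling chain of Fc receptors, rose by 0.71 (SE 0.12, adjusted p = 0.026) as the 1 riser of 23 microglia and macrophage genes. In that list 5 rose adjusted over the list alone (median 0.32, camera adjusted p = 1.6e-17).

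Chemokine and cytokine genes were higher as a list at 24 h (median 0.34, camera adjusted p = 2.9e-15). With limma 0 of 24 passed and 9 had an unadjusted p under 0.05, while 7 rose adjusted over the list alone and with the block. Cxcl1, which attracts neutrophils, stood at 0.87 (SE 0.19, adjusted p = 0.16, and 0.011 with the block). Ccl2, which attracts monocytes, stood at 0.80 (SE 0.21, adjusted p = 0.39, and 6e-04 with the block). Matrix and wound repair genes were higher with 1 riser, Mmp3, of 18 (median 0.08, camera adjusted p = 0.00015), and immediate early genes were now higher (median 0.15, camera adjusted p = 0.00016).

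Cone genes were lower at 24 h. These genes, which carry daylight vision, had a median of -0.21 (camera adjusted p = 2.7e-05), with 0 of 10 past limma, 2 at unadjusted p under 0.05 and 2 that fell adjusted over the list alone. Arr3, cone arrestin, stood at -0.69 (SE 0.21, adjusted p = 0.65, and 0.0024 with the block), and Opn1sw, the short-wave cone opsin, at -0.62 (SE 0.15, adjusted p = 0.29, and 0.0039 with the block). Mueller glia genes for glutamate, water and retinoid handling had a median of -0.24 (camera adjusted p = 2.2e-07, but adjusted p = 0.085 with an estimated correlation). With limma 0 of 13 passed and 6 had an unadjusted p under 0.05, while 4 fell adjusted over the list alone and 6 with the block. Abca8a, a lipid transporter, stood at -0.68 (SE 0.14, adjusted p = 0.10, and 9e-04 with the block). Rod genes had a median of -0.07 (camera adjusted p = 0.0084, but adjusted p = 0.22 with an estimated correlation), and lens genes no longer differed (camera adjusted p = 0.41).

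At 24 h 27 probe sets passed, 24 higher and 3 lower, for 18 named genes higher and 1 lower, Anks3 (-0.68, adjusted p = 0.043). With the block 201 passed (139 higher, 62 lower), with only replicates 2 and 3 153, and with only the 6 arrays compared 2. Omitting single arrays gave 11 to 37, and Slfn4, Oasl2, Cfb, Lcn2, Rsad2 and Ifit1 passed every time, while the 2 left with the 6 arrays alone were Slfn4 and Lcn2.

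The comparison at 7 d asked what differs once the folds have resolved. Collagen, matrix and macrophage genes were higher with INS37217, and no probe set passed as lower without the block. Col3a1 and Col1a2, fibrillar collagens of connective tissue and scar, rose by 1.97 (SE 0.20, adjusted p = 0.00029) and 1.55 (SE 0.17, adjusted p = 0.00051), Col3a1 with 0.34 to 1.97 over its probe sets. Postn, a matrix protein of activated fibroblasts, rose by 1.33 (SE 0.14, adjusted p = 0.00037). Fn1, fibronectin, rose by 1.42 (SE 0.11, adjusted p = 1.6e-05), with values of 0.03 to 1.42 over its probe sets. The fibroblast list was higher (12 of 13 genes, median 0.42, camera adjusted p = 5.5e-26), with 3 risers, 7 adjusted over the list alone and 6 with the block. The matrix and wound repair list was higher in 17 of 18 genes (median 0.40, camera adjusted p = 4.9e-32), with 1 riser, 9 adjusted over the list alone and 8 with the block. Contractile genes of the endothelium and pericyte list stayed short of the test: Tagln 1.01 (SE 0.21, adjusted p = 0.12, and 8.4e-06 with the block) and Acta2 0.61 (SE 0.12, adjusted p = 0.056, and 9e-04 with the block). The mean of that list moved less, 6.8 against 6.74. Which cells carried these genes was not tested.

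Macrophage genes at 7 d were led by Arg1, an enzyme of wound-healing macrophages, which rose by 3.23 (9.40-fold, SE 0.47, adjusted p = 0.0064), with replicate 1 at 6.15 and replicates 2 and 3 at 8.15 and 8.32 against a saline mean of 4.31. That saline mean lay below the mean of the extraocular muscle list in the same group, 5.33, so it may be background and the fold is approximate. Ccl6, a macrophage chemokine, rose by 1.95 (SE 0.30, adjusted p = 0.0092), with 0.8 to 1.95 over its 2 probe sets, of which 1 passed. Lyz2, the lysozyme of myeloid cells, rose by 1.22 (SE 0.14, adjusted p = 0.00071), and Cd74, the invariant chain of antigen presentation, by 0.87 (SE 0.14, adjusted p = 0.016). F13a1, a transglutaminase of tissue macrophages, rose by 1.09 (SE 0.16, adjusted p = 0.0064), and Pf4, a chemokine of platelets and macrophages, by 1.06 (SE 0.14, adjusted p = 0.0038). In the microglia and macrophage list 22 of 23 genes were higher (median 0.36, camera adjusted p = 1.3e-36), with 3 risers, 10 adjusted over the list alone and 9 with the block. Ptprc, the pan-leukocyte antigen, stood at 0.95 (SE 0.22, adjusted p = 0.27, and 0.0037 with the block), and Cd68, a lysosomal protein of macrophages, at 0.93 (SE 0.24, adjusted p = 0.39, and 0.022 with the block).

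Reactive glia genes stayed higher at 7 d (median 0.27, camera adjusted p = 1.9e-17), with 2 risers of 18 and 5 with the block. Serpina3n, a protease inhibitor of reactive astrocytes, rose by 1.54 (SE 0.16, adjusted p = 0.00029), and Timp1, an inhibitor of matrix proteases, by 0.96 (SE 0.15, adjusted p = 0.012). Gfap, the filament of stressed Mueller glia, stood at 0.47 (SE 0.32, adjusted p = 1, and 0.039 with the block). All 11 complement genes were higher (median 0.24, camera adjusted p = 1.8e-10), though with limma 0 passed and 3 had an unadjusted p under 0.05. Interferon and antigen presentation genes were higher (median 0.14, camera adjusted p = 4.9e-07), with 0 of 22 past limma and 4 at unadjusted p under 0.05. Amacrine and horizontal cell genes were lower (median -0.17, camera adjusted p = 0.0013), and cone genes too (median -0.10, camera adjusted p = 0.021, but adjusted p = 0.12 with an estimated correlation). In both lists 0 genes passed limma as lower.

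At 7 d 34 probe sets passed, all higher, for 25 named genes. With the block 145 passed (144 higher, 1 lower), with only replicates 2 and 3 129, and with only the 6 arrays compared 0 in limma (262 at unadjusted p under 0.05). The range with single arrays left out was 16 to 45, and Col3a1, Col1a2, Serpina3n, Fn1, Postn, Lyz2 and Pf4 passed each time.

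**Figure D2:**
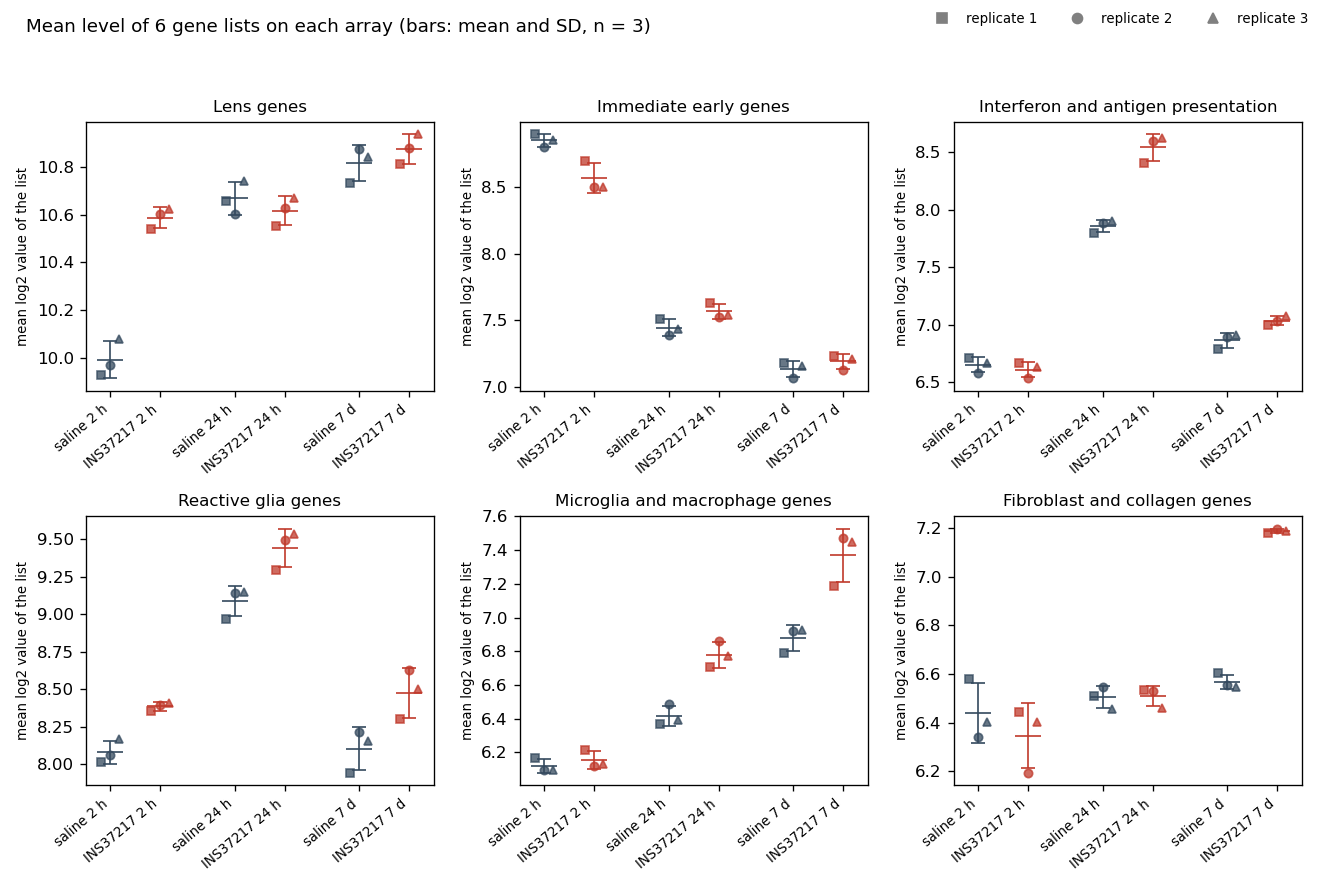
Mean log2 value of 6 gene lists on each array (lens, immediate early, interferon and antigen presentation, reactive glia, microglia and macrophages, fibroblasts and collagens) with the mean and SD of each group (n = 3), saline dark and INS37217 red. The lens list differs at 2 h, the interferon list peaks at 24 h, and the fibroblast list is highest in the INS37217 7 d group.

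**Figure D3:**
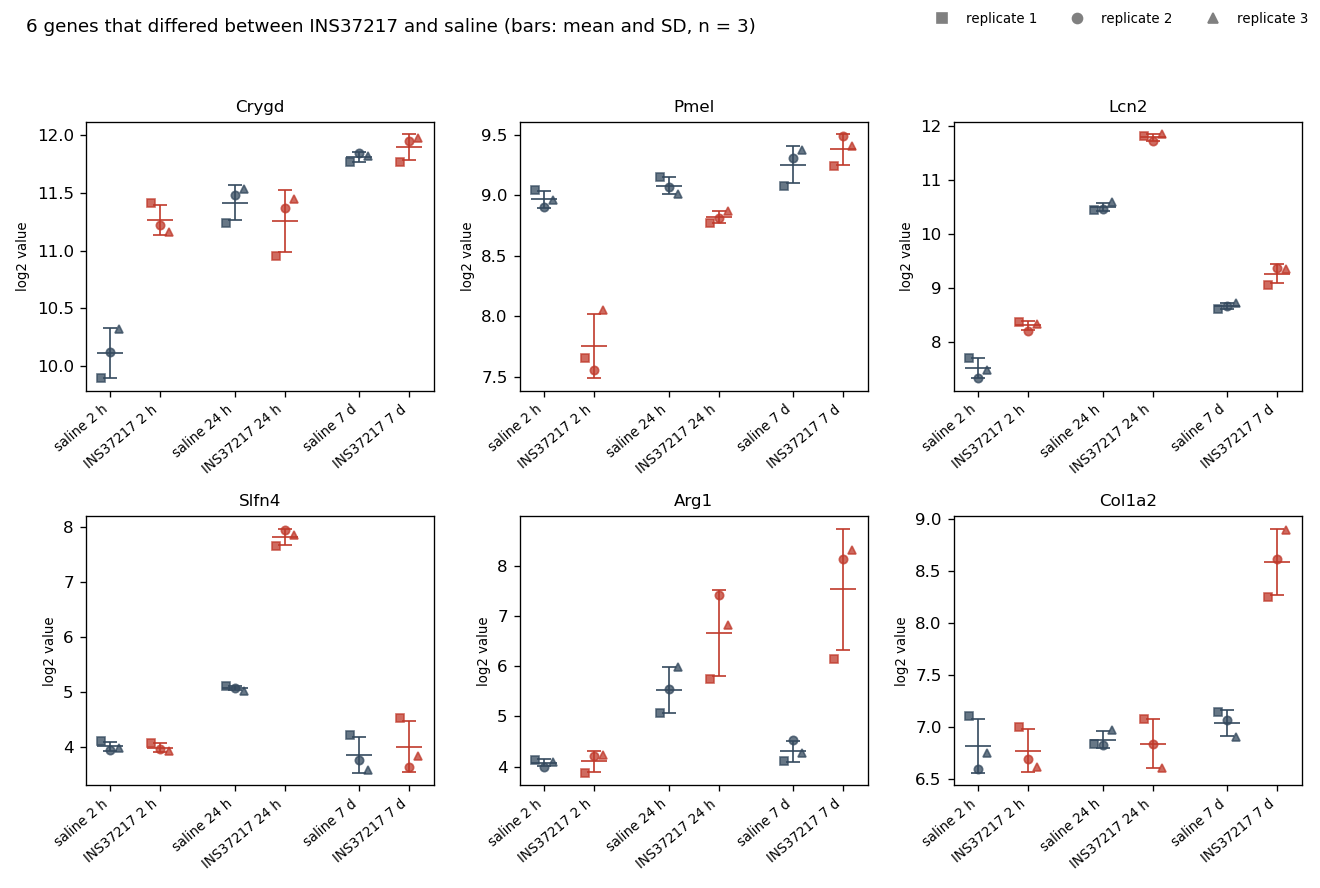
Log2 values of Crygd, Pmel, Lcn2, Slfn4, Arg1 and Col1a2 on each array, with the mean and SD of each group (n = 3), saline dark and INS37217 red.

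The saline arrays at 24 h against 2 h asked how the detached retina changes as it reattaches without the drug. Immediate early and cytokine genes fell from their 2 h level, rod genes fell, and interferon, glial, complement and lens genes rose. Egr1 and Fos, transcription factors of the early response, fell by 2.81 (SE 0.13, adjusted p = 3e-09) and 2.67 (SE 0.19, adjusted p = 3.2e-07). Of 29 immediate early genes 18 fell and 0 rose, and 22 fell adjusted over the list alone (median -1.28, camera adjusted p = 1.1e-28). Maff, a stress-induced transcription factor, fell by 4.29 (19.6-fold, SE 0.18, adjusted p = 1.1e-09). Il6, an injury cytokine, fell by 3.78 (SE 0.32, adjusted p = 1.8e-06), and Cxcl1 by 3.55 (SE 0.19, adjusted p = 2.1e-08). Of 24 cytokine, chemokine and adhesion genes 12 fell and 2 rose (median -0.48, camera adjusted p = 1.2e-09).

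Photoreceptor genes fell in saline over the same day. Prph2, which shapes outer segment discs, fell by 2.09 (SE 0.15, adjusted p = 3.8e-07), and Rdh12, a retinal reductase of the inner segment, by 0.90 (SE 0.11, adjusted p = 8.3e-05). In the rod list 12 of 25 genes fell, 16 adjusted over the list alone and 17 with the block (median -0.36, camera adjusted p = 2e-10). Opn1sw fell by 1.56 (SE 0.15, adjusted p = 8.3e-06), as 1 of 4 cone genes that fell, while 1 cone gene, Gnb3, rose (median -0.42, camera adjusted p = 0.012, but adjusted p = 0.096 with an estimated correlation). In Mueller glia Glul, glutamine synthetase, fell by 1.27 (SE 0.17, adjusted p = 0.00021), and Car14, a carbonic anhydrase, by 1.29 (SE 0.14, adjusted p = 2.4e-05), among 4 of 13 genes that fell against 1 that rose (camera adjusted p = 0.55).

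Defence and injury genes rose in saline by 24 h. Tap1, which loads peptides for antigen presentation, rose by 2.53 on its brightest probe set (SE 0.18, adjusted p = 2.6e-07), the only 1 of 4 to pass, with -0.10 as the lowest. Irf9, part of the interferon signalling complex, rose by 2.53 (SE 0.23, adjusted p = 4.8e-06), and Usp18, which damps that signal, by 2.36 (SE 0.25, adjusted p = 1.6e-05). In the interferon list 16 of 22 genes rose and 0 fell (median 1.35, camera adjusted p = 3.9e-22). Edn2, an endothelin that stressed photoreceptors make, rose most, by 3.42 (10.7-fold, SE 0.12, adjusted p = 3.9e-10). Lcn2 rose by 2.99 (SE 0.11, adjusted p = 3.9e-10), Fgf2, a photoreceptor survival factor, by 1.77 (SE 0.37, adjusted p = 0.0069), and Gfap by 1.17 (SE 0.32, adjusted p = 0.035). Of 18 reactive glia genes 11 rose and 2 fell (median 1.07, camera adjusted p = 4.5e-14). Serping1, the C1 inhibitor, rose by 1.45 (SE 0.24, adjusted p = 0.0012), with 6 of 11 complement genes (median 0.55, camera adjusted p = 2.6e-05). Apart from these, Crygd rose by 1.31 (SE 0.14, adjusted p = 2.6e-05), with 14 of 19 lens genes (median 0.62, camera adjusted p = 5.2e-20). The saline 2 h group was the lowest of all in lens genes, at 9.99 against 10.59 to 10.88, and the highest in the 3' minus 5' signal of beta-actin, at 1.04 against 0.603 to 0.747.

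In all 1714 probe sets passed, 1051 higher and 663 lower, for 845 and 516 named genes, and with equal array medians the split was 895 higher and 815 lower. With the block 6564 passed (3638 higher, 2926 lower), with only replicates 2 and 3 6100, with 1 mean per gene 958 genes, and with only the 6 arrays compared 1100. The lowest count with 1 array left out was 952, and 64 of the 82 named genes that passed did so every time.

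From 24 h to 7 d in saline, the question was what recovers as the folds resolve. The interferon and glial response receded, photoreceptor, Mueller glia and pigment epithelium lists shifted upward, and so did that of microglia and macrophages. Usp18 fell by 2.31 (SE 0.25, adjusted p = 6.5e-05) and Tap1, on the same probe set, by 2.26 (SE 0.18, adjusted p = 4e-06), and of the interferon list 11 of 22 fell and 16 adjusted over the list alone (median -0.85, camera adjusted p = 7.4e-33). Lcn2 fell by 1.83 (SE 0.11, adjusted p = 9.3e-07), with 9 of 18 reactive glia genes (median -0.87, camera adjusted p = 3.9e-31). S100a9 fell by 2.26 (SE 0.26, adjusted p = 0.00016). Junb and Atf3, of the early response, fell by 1.51 (SE 0.13, adjusted p = 1.2e-05) and 1.40 (SE 0.10, adjusted p = 2e-06), with 5 of 29 immediate early genes (median -0.22, camera adjusted p = 1.8e-07). Ccl2 fell by 1.23 (SE 0.21, adjusted p = 0.0055), as 1 of 2 cytokine genes that fell (median -0.11, camera adjusted p = 0.02, but adjusted p = 0.2 with an estimated correlation).

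The cone, rod, Mueller glia and pigment epithelium lists shifted upward in saline over that time, mostly with few single genes past the test. Opn1sw rose by 1.19 (SE 0.15, adjusted p = 0.00037), 1 of 3 risers among 10 cone genes (median 0.30, camera adjusted p = 1.8e-05). Rdh12 rose by 0.53 (SE 0.11, adjusted p = 0.024), the 1 riser of 25 rod genes, where 5 rose adjusted over the list alone (median 0.20, camera adjusted p = 1.8e-07). Prph2 did not recover, with saline means of 10.08 at 2 h, 7.99 at 24 h and 7.77 at 7 d. Car14 rose by 1.32 (SE 0.14, adjusted p = 6.2e-05) and Glul by 1.08 (SE 0.17, adjusted p = 0.0027), among 4 risers of 13 Mueller glia genes (median 0.58, camera adjusted p = 1.8e-11). Rpe65, the visual cycle isomerase, rose by 1.25 (SE 0.12, adjusted p = 2.2e-05), the 1 riser of 13 pigment epithelium genes, where 8 rose adjusted over the list alone (median 0.48, camera adjusted p = 1e-10). Csf1r, a growth factor receptor of microglia and macrophages, rose by 1.79 (SE 0.19, adjusted p = 6.5e-05), with 0.63 to 1.79 over its probe sets. P2ry12, a nucleotide receptor of resting microglia, rose by 1.63 (SE 0.20, adjusted p = 0.00021), and C1qa, which microglia secrete, by 1.45 (SE 0.14, adjusted p = 2.8e-05). Of 23 microglia and macrophage genes 5 rose and 1 fell, and 11 rose and 2 fell adjusted over the list alone (median 0.38, camera adjusted p = 5.8e-09). Among the genes chosen for naming the largest rises were Spc25 (2.48, SE 0.18, adjusted p = 1.6e-06) and Lyz2 (2.12, SE 0.14, adjusted p = 1.2e-06). Spc25 had 0.78 to 2.48 over its probe sets.

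From 24 h to 7 d in saline 297 probe sets passed, 76 higher and 221 lower, for 67 and 176 named genes. With the block 1668 passed (615 higher, 1053 lower), with only replicates 2 and 3 1002, and with only the 6 arrays compared 78. Single omissions gave 165 to 228, and 36 of 50 named genes passed in all of them.

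The INS37217 arrays asked whether the same course is run with the drug. Of the 1051 probe sets that rose in saline from 2 h to 24 h 1021 had the same sign with INS37217, and the interferon genes rose further. Slfn4 rose by 3.82 from 2 h to 24 h (14.1-fold, SE 0.19, adjusted p = 3.8e-09), Oasl2 by 3.73 (SE 0.14, adjusted p = 3.5e-10) and Ifit1 by 3.10 (SE 0.16, adjusted p = 3.8e-09), with 19 of 22 interferon genes (median 2.23, camera adjusted p = 8.6e-43). The fold of Slfn4 is approximate, since its INS37217 2 h values, 3.94 to 4.08, lay below the mean of the extraocular muscle list there, 5.46. Maff fell by 4.16 (SE 0.18, adjusted p = 2e-09) and Il6 fell by 3.91 (SE 0.32, adjusted p = 8.8e-07). Of the immediate early genes 16 of 29 fell (median -0.80, camera adjusted p = 9.1e-17). Prph2 fell by 2.45 (SE 0.15, adjusted p = 4.3e-08), with 16 of 25 rod genes (median -0.51, camera adjusted p = 6.1e-15), and Opn1sw by 2.19 (SE 0.15, adjusted p = 1.4e-07), with 5 of 10 cone genes (median -0.59, camera adjusted p = 8.8e-06). Of the microglia and macrophage genes several rose by 24 h (11 rose and 1 fell of 23, median 0.49, camera adjusted p = 5.9e-10), while lens genes had 0 past limma and did not shift (camera adjusted p = 0.24).

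From 24 h to 7 d with INS37217 the interferon genes fell back (18 of 22, median -1.58, camera adjusted p = 1.6e-58), Slfn4 by 3.81 (SE 0.19, adjusted p = 2.6e-08) and Oasl2 fell by 2.64 (SE 0.14, adjusted p = 2.7e-08). S100a9 fell by 3.69 (SE 0.26, adjusted p = 6.2e-07) and Lcn2 by 2.54 (SE 0.11, adjusted p = 9e-09). Lyz2 rose by 2.71 (SE 0.14, adjusted p = 2.7e-08), with 9 of 23 microglia and macrophage genes (median 0.45, camera adjusted p = 4.6e-13). In saline Lyz2 rose by 2.12 over the same time. Col1a2 rose by 1.75 (SE 0.17, adjusted p = 1.8e-05), with 5 of 13 fibroblast genes (median 0.74, camera adjusted p = 3.3e-13), a list that did not pass in saline. Car14 rose by 1.84 (SE 0.14, adjusted p = 1.2e-06) and Rlbp1, a retinoid carrier, by 1.54 (SE 0.25, adjusted p = 0.0022), with 7 of 13 Mueller glia genes (median 1.07, camera adjusted p = 9.1e-19). Opn1sw rose by 1.61 (SE 0.15, adjusted p = 1e-05), with 3 of 10 cone genes (median 0.43, camera adjusted p = 6.3e-08), and 3 rod genes rose while 1, Prph2, fell by 0.67 (SE 0.15, adjusted p = 0.028; list median 0.24, camera adjusted p = 1.6e-09).

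With INS37217 1476 probe sets passed from 2 h to 24 h (730 higher, 746 lower) and 501 from 24 h to 7 d (213 higher, 288 lower), for 552, 586, 166 and 214 named genes. The courses rest on separate arrays but share 1 estimate of the spread per probe set, so their calls are not independent. From 2 h to 24 h 499 probe sets rose in both (33.9 if the calls were independent) and 473 fell in both (21.9). From 24 h to 7 d 61 rose in both (0.715) and 169 fell in both (2.81). Across probe sets, which are not independent replicates, the changes correlated at r = 0.842 and 0.701. With the block 5002 (2626 higher, 2376 lower) and 1733 (812 higher, 921 lower) passed, with only replicates 2 and 3 5167 and 1401, and with only the 6 arrays compared 935 and 134. The lowest counts with 1 array left out were 924 and 320, and 74 of 88 and 47 of 63 named genes passed each time.

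The interactions asked which genes change over time by another amount with INS37217 than with saline. From 2 h to 24 h interferon genes rose further with INS37217: Slfn4 by 2.76 more (SE 0.27, adjusted p = 0.00069), Ifit1 by 1.74 (SE 0.22, adjusted p = 0.0057), Rsad2 by 1.62 (SE 0.21, adjusted p = 0.0057) and Oasl2 by 1.59 (SE 0.20, adjusted p = 0.0057). Of 22 interferon genes 3 passed, all higher, and 9 adjusted over the list alone (median 0.50, camera adjusted p = 3.4e-38). Lens genes, already higher at 2 h, rose less with INS37217: Crygd by -1.31 (SE 0.20, adjusted p = 0.026) and Crygf by -0.89 (SE 0.15, adjusted p = 0.039), 2 of 19, and 13 adjusted over the list alone (median -0.69, camera adjusted p = 7.8e-45). Immediate early genes fell less (median 0.35, camera adjusted p = 1.1e-17), with 0 of 29 past limma, 10 at unadjusted p under 0.05 and 7 adjusted over the list alone. Egr2 stood at 1.20 (SE 0.29, adjusted p = 0.39, and 0.0037 with the block). From 24 h to 7 d matrix genes changed upward with INS37217 relative to saline: Col1a2 by 1.59 (SE 0.25, adjusted p = 0.033), Postn by 1.48 (SE 0.20, adjusted p = 0.011) and Fn1 by 1.21 (SE 0.16, adjusted p = 0.0091), with -0.07 to 1.21 over its probe sets. Col3a1 stood at 1.61 (SE 0.29, adjusted p = 0.087, and 0.0015 with the block). Of 13 fibroblast genes 2 passed and 4 adjusted over the list alone (median 0.40, camera adjusted p = 1.8e-17), while the interferon list fell further (1 of 22, 4 adjusted over the list alone, median -0.44, camera adjusted p = 3.8e-23).

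The interaction counts were small: 13 probe sets (7 higher, 6 lower) from 2 h to 24 h and 9 (7 higher, 2 lower) from 24 h to 7 d. With the block they were 242 (100 higher, 142 lower) and 62 (40 higher, 22 lower), with only replicates 2 and 3 177 and 51, with only the 12 arrays compared 8 and 1 (592 and 342 at unadjusted p under 0.05), and with single arrays left out 4 to 14 and 3 to 12.

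The average over the times asked which genes differ over the mean of the 3 times. The lists of reactive glia, microglia and macrophages, complement, and matrix and wound repair were higher, and Alas2 and Pmel fell. Lcn2 rose by 0.89 (SE 0.07, adjusted p = 1.2e-05), Serpina3n by 0.75 (SE 0.09, adjusted p = 0.0027) and Timp1 by 0.69 (SE 0.09, adjusted p = 0.0027), the 3 risers of 18 reactive glia genes, where 9 rose adjusted over the list alone (median 0.31, camera adjusted p = 5.5e-24). Arg1 rose by 1.46 (SE 0.27, adjusted p = 0.041), Chil1 by 0.75 (SE 0.11, adjusted p = 0.0075) and Lyz2 by 0.58 (SE 0.08, adjusted p = 0.0071). Of 23 microglia and macrophage genes 3 rose, and 15 adjusted over the list alone (median 0.28, camera adjusted p = 2.1e-27). Cfb rose by 0.64 (SE 0.10, adjusted p = 0.012), the 1 riser of 11 complement genes (median 0.13, camera adjusted p = 7.9e-08), and Fn1 by 0.51 (SE 0.06, adjusted p = 0.0027), with -0.04 to 0.51 over its probe sets, as the 1 riser of 18 matrix and wound repair genes (median 0.21, camera adjusted p = 8.8e-17). Alas2 fell by 0.71 (SE 0.10, adjusted p = 0.0075) and Pmel by 0.45 (SE 0.07, adjusted p = 0.014). Single times carried some of these averages: at 2 h, 24 h and 7 d Arg1 stood at 0.02, 1.13 and 3.23, Fn1 at -0.10, 0.21 and 1.42, and Pmel at -1.22, -0.26 and 0.13. In all 47 probe sets passed, 41 higher and 6 lower, for 31 and 4 named genes, the 4 being Alas2, Pmel, Anks3 (-0.38) and Dio2 (-0.50). With the block 349 passed (260 higher, 89 lower), with only replicates 2 and 3 278, and 26 to 50 with 1 array left out, and 11 of 16 named genes passed each time.

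For the target of INS37217 and for the water channels no difference between treatments passed without the block. P2ry2, the receptor itself, stood at 0.11, 0.12 and -0.06 at 2 h, 24 h and 7 d (SE 0.11, adjusted p = 1 at each). Its group means, 5.3 to 5.47, lay near the median level of the extraocular muscle genes, 5.22, so its probe set may be unable to show a change. Aqp1, a water channel of photoreceptors and amacrine cells, stood at 0, -0.14 and 0.14 (SE 0.10), and Aqp4, that of Mueller glia, at 0.17, -0.04 and -0.15 (SE 0.32), adjusted p = 1 throughout. Mip, the water channel of lens fibres, stood at 0.71 at 2 h (SE 0.18, adjusted p = 0.29, and 0.006 with the block), -0.10 at 24 h and 0.24 at 7 d (adjusted p = 1 at both). Fgf2 stood at 0.01, 0.13 and -0.26, again with adjusted p = 1. Over time Aqp1 fell by 0.46 from 2 h to 24 h with INS37217 (SE 0.10, adjusted p = 0.0091) and rose by 0.44 by 7 d (adjusted p = 0.025), while in saline it stood at -0.32 (adjusted p = 0.065, and 0.0076 with the block) from 2 h to 24 h. Purinergic receptor and ectonucleotidase genes were higher as a list with INS37217 at 2 h (median 0.11, camera adjusted p = 0.0011, but adjusted p = 0.16 with an estimated correlation), with 0 of 15 past limma and 1 at unadjusted p under 0.05. That gene was Nt5e, which makes adenosine (0.54, SE 0.10, adjusted p = 0.056, and 0.0018 with the block).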

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

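Among the tests weighed here, those of the lens genes, of the signal range of replicate 1, of scleral tissue and of macrophages were chosen only after the result was seen, while those of the cell mix in replicate 1, of the genes that rose in saline and of random splits were fixed earlier.

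The first pattern was the higher lens gene signal with INS37217 at 2 h (camera adjusted p = 3.3e-61), where Crygd had 1.15. Lens tissue in unequal amounts in the 2 h pools may explain it, since the 5 lens genes that are not crystallins had a median change of 0.53 (0.18 to 0.97) beside 0.64 (0.29 to 1.15) for the 14 crystallins. The lowest lens mean of the INS37217 2 h arrays lay 0.46 above the highest of the saline 2 h arrays, so no single array stood among the other group. That cannot exclude a single 2 h array under the wrong treatment label. The lens list was chosen because it parts these groups, and its level may follow the lens tissue of a pool rather than the treatment. An induction of crystallins in the retina by INS37217 is a hypothesis. If it reached crystallins alone it would leave the other lens genes unmoved, which they were not. An induction of lens genes together would raise both sets, so these values cannot tell it from unequal lens tissue. An exchange of the whole groups, and whether the saline 2 h pools held less lens or the INS37217 pools more, stay open.

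The second pattern was that replicate 1 stood apart from replicates 2 and 3 in all 6 groups. A compressed signal range on those arrays would lower bright and raise dim probe sets, and the correlation of the replicate 1 deviation with the mean level was -0.223 in the weakest group and -0.356 in the strongest. The dimmest 25% of probe sets deviated by 0.05 to 0.17 and the brightest 25% by -0.15 to -0.33, which leaves most of the deviation unexplained. Another mix of cells in the replicate 1 pools could be the reason, but 0 of 12 cell type lists passed once the trend with the level was removed (camera adjusted p = 0.81 at the lowest, with an estimated correlation), while list medians as far from 0 as 0.39 for neutrophils, 0.21 for erythrocytes and -0.17 for pigment epithelium keep it open. A separate preparation of RNA or labelling stays open, as neither is described per replicate in the sources used here.

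The third pattern was the higher collagen and macrophage signal with INS37217 at 7 d, with Col3a1 at 1.97 and Arg1 at 3.23. More macrophages or microglia in those pools could account for the myeloid part, but the median of that list, 0.36, only restates the pattern. Csf1r, a receptor of macrophages as well as microglia, stood at -0.01 on the brightest of its 3 probe sets, and P2ry12, a marker of resident microglia, at -0.44. Sclera carried over with the retina would raise stromal proteoglycans and type VI collagen too, and their median was 0.14 (7 genes) beside 1.04 for the other 6 genes of the list, fibrillar collagens and Postn. That does not decide, because genes the retina already expresses would rise less, and signals of different probe sets (7.45 on average against 6.56) compare only roughly. Scar formation by fibroblasts or glia, more myeloid cells, carried-over tissue and a mixture of them stay open, and the muscle genes, at -0.18 to 0.09, speak against carried-over eye muscle.

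Whether other groupings of the same arrays might give as many calls was asked with splits of the arrays. For each of the 7 comparisons of 3 against 3 arrays there are too few splits for a share under 0.05: the real grouping was the 1 of 10 that gave as many calls, with 29 at 2 h (highest other 0), 27 at 24 h (2) and 34 at 7 d (0), and 0 in every other split of the 4 time comparisons. For the change from 2 h to 24 h 2 of 100 splits gave 13 calls or more, the highest other 18, but both lie among the 16 splits that part the replicate numbers as the real one does. Against those 16 chance cannot be excluded for its 13 calls. For the change from 24 h to 7 d 8 of 100 gave 9 calls or more, and 2 of the 19 that part the replicate numbers, with 10 as the highest other there, so chance cannot be excluded. The 6266 calls of a split that did not part them point to the structure by replicate. For the average 1 of 100 gave 47, the real one, and the highest other gave 4, but only 6 of the splits part the replicate numbers (highest other 1), too few for a share under 0.05.

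Genes whose change from 2 h to 24 h differed between treatments were 13 probe sets, 10 of them named (limma, effects of INS37217 at the earlier and later time in brackets). Interferon genes rose further with INS37217. The values were Slfn4 2.76 (SE 0.27, adjusted p = 0.00069, -0.02 and 2.74), Ifit1 1.74 (adjusted p = 0.0057, -0.56 and 1.19), Rsad2 1.62 (adjusted p = 0.0057, -0.39 and 1.24), Oasl2 1.59 (adjusted p = 0.0057, -0.13 and 1.46) and B2m, the light chain of class I antigens, 1.01 on its weaker probe set (adjusted p = 0.035, -0.19 and 0.81). The other 5 named genes had a lower change with INS37217 than with saline. Their values were Crygd -1.31 (adjusted p = 0.026, 1.15 and -0.16), Mbd1, a methyl-DNA binding protein, -1.10 (adjusted p = 0.035, 0.97 and -0.12), Hspa1b -1.01 on another probe set (adjusted p = 0.035, 1.00 and -0.01), Srxn1, an antioxidant enzyme, -0.93 on another probe set (adjusted p = 0.014, 0.72 and -0.21) and Crygf -0.89 (adjusted p = 0.039, 0.69 and -0.20).

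From 24 h to 7 d 9 probe sets differed, 8 of them named. Matrix genes had a higher change with INS37217 than with saline: Col1a1, a fibrillar collagen, 2.36 on 1 of its probe sets (SE 0.17, adjusted p = 1.5e-05, -0.11 and 2.25), Col1a2 2.26 (adjusted p = 0.024, 0.06 and 2.32) and 1.59 (adjusted p = 0.033, -0.04 and 1.55) on its probe sets, Postn 1.48 (adjusted p = 0.011, -0.15 and 1.33), Ecm1, a matrix glycoprotein, 1.22 (adjusted p = 0.038, -0.23 and 0.99) and Fn1 1.21 (adjusted p = 0.0091, 0.21 and 1.42). Interferon genes had a lower one: Slfn4 -2.60 (SE 0.27, adjusted p = 8e-04, 2.74 and 0.15) and Oasl2 -1.22 (adjusted p = 0.042, 1.46 and 0.24). The Col1a1 probe set given is not its probe set of highest mean. On the latter the difference at 7 d was no larger than the 0.74 of Col5a2. Single arrays were not tested for deviating values within their group of 3.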

How the results depend on the processing

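Of the alternative tests, only replicates 2 and 3, with or without the block, were chosen only after the result was seen. The number of probe sets past the test moved by more than 1.5 times in all 10 comparisons with the block, and it added calls for genes and took none away. The cause of the moved counts was not tested, beyond the replicate 1 arrays adding spread that the block takes out.

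INS37217 against saline at 2 h (29 probe sets) gave 398 with the block, 304 with only replicates 2 and 3, 407 with the block on those arrays, 46 after quantile normalization again and 0 with only its 6 arrays in limma (812 at unadjusted p under 0.05). With 1 array left out it gave 8 to 19: without saline 2 h replicates 1, 2 and 3 18, 10 and 18, and without INS37217 2 h replicates 1, 2 and 3 19, 16 and 8. At 24 h (27) it gave 201 with the block, 153 with replicates 2 and 3, 42 after quantile normalization again, 10 with only probe sets above the median level and 2 with only its 6 arrays. Left out singly, the arrays gave 11 to 37: saline 24 h replicates 1, 2 and 3 14, 11 and 15, and INS37217 24 h replicates 2 and 3 12 and 13. At 7 d (34) it gave 145 with the block, 129 with replicates 2 and 3, 13 above the median level and 0 with only its 6 arrays in limma (262 at unadjusted p under 0.05). Omissions gave 16 to 45: saline 7 d replicates 2 and 3 20 each, INS37217 7 d replicates 2 and 3 16 each.

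Saline at 24 h against 2 h (1714) gave 6564 with the block, 6100 with replicates 2 and 3, 958 with the mean of the probe sets of a gene and 1100 with only its arrays. Omissions gave 952 to 1721: 987 without saline 2 h replicate 2, 965 and 952 without saline 24 h replicates 2 and 3. Saline at 7 d against 24 h (297) gave 1668 with the block, 1002 with replicates 2 and 3 and 78 with only its arrays. Omissions gave 165 to 228: 175 and 165 without saline 24 h replicates 2 and 3, 181 without saline 7 d replicate 3. INS37217 at 24 h against 2 h (1476) gave 5002 with the block, 5167 with replicates 2 and 3 and 935 with only its arrays, and 924 to 1342 on omission, 924 and 946 without INS37217 24 h replicates 2 and 3. INS37217 at 7 d against 24 h (501) gave 1733, 1401 and 134, the first of them with the block, and 320 to 449 on omission, 320 and 323 without INS37217 24 h replicates 2 and 3.

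The change from 2 h to 24 h, INS37217 minus saline (13), gave 242 with the block, 177 with replicates 2 and 3, 25 after quantile normalization again and 8 with only its 12 arrays. Omissions gave 4 to 14: 4 without saline 2 h replicate 2, 6 and 5 without saline 24 h replicates 2 and 3, 4 and 6 without INS37217 2 h replicates 1 and 2, 6 and 5 without INS37217 24 h replicates 2 and 3. Its share of higher probe sets was 53.8%, 64% after quantile normalization again and 78.6% with equal array medians. The change from 24 h to 7 d (9) gave 62 with the block, 51 with replicates 2 and 3, 5 above the median level and 1 with only its 12 arrays. Omissions gave 3 to 12: 3 without saline 24 h replicate 2, 5 each without saline 7 d replicates 2 and 3, INS37217 24 h replicate 2 and INS37217 7 d replicate 2, and 4 without INS37217 7 d replicate 3. The average (47) gave 349 with the block, 278 with replicates 2 and 3, 24 above the median level, and 26 to 50 on omission. It gave 26 and 27 without saline 2 h replicates 2 and 3, 29, 30 and 30 without saline 24 h replicates 1, 2 and 3, and 26 and 28 without saline 7 d replicates 2 and 3. Without INS37217 2 h replicates 1 and 3 it gave 30 and 26, without INS37217 24 h replicates 2 and 3 26 and 27, and without INS37217 7 d replicates 2 and 3 28 and 29.

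Of 280 list tests 144 passed, 81 of them also with an estimated correlation, and none passed only there. With the block 140 passed, and 131 to 146 with 1 array left out. Of the 144 calls 46 were lost with at least 1 array left out, 27 with only replicates 2 and 3, and 26 with only probe sets above the median level, where 1 more changed direction. The block took the call from transport genes at 24 h (camera adjusted p = 0.066), neutrophils in INS37217 from 2 h to 24 h (0.051), hypoxia genes in INS37217 from 24 h to 7 d (0.12) and in the change from 2 h to 24 h (0.09), transport genes in the change from 24 h to 7 d (0.066) and cornea genes in the average (0.073). It added cytokines at 7 d (0.025) and cone genes in the change from 24 h to 7 d (0.028). The complement list at 24 h, median 0.17, stood at -0.11 with only probe sets above the median level (camera adjusted p = 1) and at 0 to 0.28 with 1 array left out.

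Genes near 0 between treatments changed sign, and none of them passed there (adjusted p = 0.9 at the lowest). At 2 h Aqp1 (0) stood at 0 after quantile normalization again and at -0.05 to 0.06 on omission of 1 array. Fgf2 (0.01) stood at -0.02 after quantile normalization again, -0.02 with equal medians, -0.06 with replicates 2 and 3, -0.06 with the block on those, and -0.07 to 0.09 on omission. Gfap (0.15) ranged from -0.10 to 0.39 on omission. At 24 h Aqp4 (-0.04) stood at 0.02 after quantile normalization again and -0.41 to 0.20 on omission, and Gfap (-0.03) at 0.02 and -0.24 to 0.18. On omission at 24 h Cryaa (0.05) ranged from -0.04 to 0.14, Cryab (0.04) from -0.03 to 0.07, Fgf2 (0.13) from -0.30 to 0.52 and Mip (-0.10) from -0.22 to 0.04. At 7 d Aqp4 (-0.15) ranged from -0.39 to 0.11 and P2ry2 (-0.06) from -0.14 to 0.02. Cflar, an inhibitor of death receptors, fell by 0.64 in INS37217 from 2 h to 24 h but stood at 0.03 as the mean of its probe sets (adjusted p = 0.88).

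Of the 350 calls of named genes all passed with the block, 3 were lost with only replicates 2 and 3, 96 with at least 1 array left out, 24 with the mean of the probe sets of a gene, 22 after quantile normalization again, 13 with trend and robust and 12 with equal medians. Of the 334 that can be tested with only the arrays compared 113 were lost there.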

Other observations

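None of the tests in this part was chosen only after the result was seen. Top2a, Rrm1 and Mcm7 of the cell cycle list rose in saline by 24 h, each on only 1 of its probe sets. Top2a, a topoisomerase of dividing cells, changed by 0.77 (SE 0.14, adjusted p = 0.0022, n = 3) with -0.30 on its other probe set, Rrm1, which supplies nucleotides for DNA synthesis, by 0.97 (SE 0.21, adjusted p = 0.011) with 0.12 on the other, and Mcm7, part of the replication helicase, by 0.65 (SE 0.16, adjusted p = 0.017), while Cdkn1a, a brake on the cycle, fell by 0.93 (SE 0.17, adjusted p = 0.0025). Of 28 cell cycle genes 5 rose and 1 fell, and 9 rose adjusted over the list alone (median 0.16, camera adjusted p = 0.0044, but adjusted p = 0.086 with an estimated correlation). By 7 d in saline Top2a fell by 0.87 (SE 0.14, adjusted p = 0.0027) with 0.27 on its other probe set, while Bub1b, a checkpoint kinase of mitosis, rose by 0.55 (SE 0.10, adjusted p = 0.0084), and adjusted over the list alone 5 genes fell and 1 rose (median -0.16, camera adjusted p = 0.0011, but adjusted p = 0.054 with an estimated correlation). With INS37217 the list had medians of 0.19 and then -0.09 (camera adjusted p = 0.0045 and 0.01, but adjusted p = 0.087 and 0.12 with an estimated correlation). INS37217 against saline did not pass for it at any time (camera adjusted p = 0.66, 0.88 and 0.22).

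Single growth factor and cell death genes fell from 2 h to 24 h while their lists did not shift in saline. Lif, a cytokine by which Mueller glia protect photoreceptors, fell by 2.32 in saline (SE 0.19, adjusted p = 1.1e-06) with -0.12 on its other probe set, and Hbegf, a growth factor of glial proliferation, by 1.42 (SE 0.14, adjusted p = 1.4e-05). Of 17 growth and neurotrophic factors 3 fell and 1 rose, Met, the receptor of hepatocyte growth factor, at 0.92 (list median -0.06, camera adjusted p = 0.078). With INS37217 4 fell (median -0.20, camera adjusted p = 0.026, but adjusted p = 0.062 with an estimated correlation). Among 20 cell death genes Birc3, an inhibitor of apoptosis, fell by 0.77 (SE 0.11, adjusted p = 0.00036) and Bcl2l11, which promotes it, by 0.73 (SE 0.17, adjusted p = 0.015; -0.73 to 0.21 over its probe sets), with 4 lower and 1 higher and no shift of the list (camera adjusted p = 0.17). Cell death genes were higher with INS37217 at 24 h (median 0.11, camera adjusted p = 0.0048, but adjusted p = 0.16 with an estimated correlation), with 0 past limma and 3 at unadjusted p under 0.05. Adm, a vasodilator peptide induced by hypoxia, fell by 0.98 in saline by 24 h (SE 0.13, adjusted p = 0.00012), and Pfkfb3, a switch of glycolysis, by 0.72 (SE 0.11, adjusted p = 0.00081; 0.18 on its other probe set), the 2 of 22 hypoxia and glycolysis genes that passed. That list had a median of 0.01 and a mean of -0.08 (camera direction lower, adjusted p = 0.73). Hypoxia genes were lower with INS37217 at 24 h (median -0.10, camera adjusted p = 0.0095, but adjusted p = 0.098 with an estimated correlation).

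Single vessel, cornea and inner retina genes changed with time. Kdr, the main receptor of VEGF on endothelium, rose by 0.75 in saline by 24 h (SE 0.13, adjusted p = 0.0022), and Flt1, its decoy, fell by 0.69 (SE 0.18, adjusted p = 0.027), with 2 higher and 1 lower of 17 endothelium and pericyte genes (camera adjusted p = 0.28). At 2 h that list was lower with INS37217 (median -0.04, camera adjusted p = 0.014, but adjusted p = 0.062 with an estimated correlation). Aldh3a1, an aldehyde dehydrogenase abundant in cornea, rose by 1.93 (SE 0.13, adjusted p = 1.3e-07), and Krt12, the corneal keratin, by 0.67 (SE 0.13, adjusted p = 0.0039), the 2 risers of 10 cornea genes, whose median was -0.02 and mean 0.21 (camera direction higher, adjusted p = 0.097). The 11 genes of extraocular muscle had 0 past limma, 0 at unadjusted p under 0.05 and no shift with INS37217 (camera adjusted p = 0.41, 0.47 and 0.88). Bipolar cell genes were lower in saline at 24 h (median -0.22, camera adjusted p = 0.017, but adjusted p = 0.054 with an estimated correlation) and higher again by 7 d (median 0.27, camera adjusted p = 0.00037). Lhx1, a transcription factor of horizontal cells, fell by 0.74 by 24 h (SE 0.16, adjusted p = 0.009), and Chrna6, a nicotinic receptor of ganglion cells, by 0.63 (SE 0.14, adjusted p = 0.011; 0.26 on its other probe set). Ganglion cell genes were lower with INS37217 at 7 d (median -0.14, camera adjusted p = 0.0018, but adjusted p = 0.24 with an estimated correlation), with 0 of 11 past limma and 0 at unadjusted p under 0.05.

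Genes of aquaporins and of ion or fluid transport were lower with INS37217 at 24 h (median -0.06, camera adjusted p = 0.043, but 0.066 with the block, and adjusted p = 0.079 with an estimated correlation). With limma 0 of 24 passed, 3 had an unadjusted p under 0.05, and 2 fell adjusted over the list alone. From 24 h to 7 d they rose, 1 gene in saline (median 0.09, camera adjusted p = 0.0035) and 3 with INS37217 (median 0.17, camera adjusted p = 8.1e-06). Aqp4 stood at 1.24 in saline (SE 0.32, adjusted p = 0.086, and 5.2e-07 with the block) and at 1.13 with INS37217 (SE 0.32, adjusted p = 0.11, and 1.2e-06 with the block). Aqp5, a water channel of secretory epithelium, rose by 0.84 in saline from 2 h to 24 h (SE 0.15, adjusted p = 0.0024). Neutrophil genes rose with INS37217 from 2 h to 24 h (2 of 12, camera adjusted p = 0.027, but 0.051 with the block, and adjusted p = 0.48 with an estimated correlation) and fell by 7 d (2 of 12, camera adjusted p = 0.00041, but adjusted p = 0.25 with an estimated correlation). Heat shock and oxidative stress genes fell from 24 h to 7 d in saline (2 of 22, median -0.27, camera adjusted p = 4.3e-07, but adjusted p = 0.086 with an estimated correlation). Erythrocyte genes fell in saline by 24 h (1 of 3, median -0.45, camera adjusted p = 0.0049, but adjusted p = 0.13 with an estimated correlation), the 1 being Alas2 at -1.58 (SE 0.18, adjusted p = 4.4e-05).

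A hypothesis is that INS37217 might strengthen the response that detachment itself evokes by 24 h. The 497 genes that rose in saline from 2 h to 24 h on their probe set of highest mean, of 845 on any probe set, had a median change of 0.003 with INS37217 at 24 h, above all of 10000 random lists of like level (percentile 100, most of them between -0.05 and -0.02), and 252 of the 497 were above 0. The saline 24 h arrays enter both sides, which biases the test against the hypothesis, but the shift itself is too small to matter for most of these genes. Single genes among them, such as Lcn2 at 1.30, carried larger differences. An alternative is that INS37217 shifts the time of the interferon peak rather than its height, which samples between 2 h and 7 d other than 24 h would be needed to tell.

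The lists that passed with INS37217 overlapped in time. Reactive glia genes were higher as a list at 2 h, 24 h and 7 d (medians 0.33, 0.27 and 0.27), though Gfap passed at none of them without the block. Cytokine genes were higher at 2 h and 24 h (0.22 and 0.34). Interferon and antigen presentation genes (0.59 and 0.14) and microglia and macrophage genes (0.32 and 0.36) were higher at 24 h and 7 d. Fibroblast genes passed at 7 d alone (0.42).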
